A study of Homo sapiens with 8 samples.

How the data were processed

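RNA that included small RNAs was isolated from HepG2 cells with a column kit, labelled with Cy3 by enzymatic extension and hybridized to 1-colour arrays with 7 spots per miRNA, per the labels' protocols. Each of the 4 groups (untreated, cacao proanthocyanidin extract at 100 mg/L, grape seed proanthocyanidin extract at 100 mg/L, and EGCG at 50 mg/L) had 2 arrays with 1 replicate on each. Treatments lasted 5 h with DMSO at a final 0.1%, and whether the untreated cells received DMSO is not given in the sources used here.

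The authors deposited a table of linear intensity, with 1 value for each of 904 human miRNAs on every array. The background had been corrected with blank probes, per the labels' protocols, and values below 0 occurred on every array. How the 7 spots were combined is not given in the sources used here. Between 87.7% and 94.4% of the values per array were multiples of 8. The authors also deposited a table of normalized values on a log2-like scale, whose normalization is not given in the sources used here. The submitters' processing notes name limma without a version. Within each array the deposited log2 value had the same rank order as the intensity (Spearman rho of 1), and at high intensities it rose with log2 intensity at a slope of 1.00 to 1.02. The deposited columns had medians of 6.15 to 6.39, so they were not centred on 0, and their exact transformation of low values stays unknown.

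The main values were computed from the intensity table. Intensities below 0 were set to 0, 50 was added, and the log2 values were quantile normalized between the 8 arrays. No further background correction was applied, because the values had already been subtracted. A fold change is therefore on the log2(intensity + 50) scale and understates the change of dim miRNAs. The tables used here held no blank or spike-in rows, so no detection call was made, and a miRNA whose mean log2 intensity lay below the median of all miRNAs (7.25) is called dim. The floor of the scale was 5.64. Without normalization between arrays, the median over all miRNAs shifted by 0.22 in cacao extract, 0.13 in grape seed extract and -0.07 in EGCG against control, by -0.09 between grape seed and cacao extracts, by -0.28 and -0.20 between EGCG and the cacao and grape seed extracts, and by 0.10 in the average of the treatments. All fold changes are relative to that shift, and after quantile normalization the medians lay within 0.02 of 0.

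Group means were fitted to all 8 arrays together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), which gave 4 residual and 5.51 prior degrees of freedom. The 7 comparisons were each treatment against control, each treatment against another and the average of the 3 treatments against control, beside a test of any difference among the groups. p-values were two-sided and adjusted by the Benjamini-Hochberg method over 904 miRNAs, and a miRNA is called at an adjusted p under 0.05. Intervals are at 95%. Both arrays of the treated group lay outside both controls for 21.6% of miRNAs in cacao extract, 25.8% in grape seed extract and 21.8% in EGCG, where chance gives 33.3% for independent arrays. Unchanged groups simulated with the shared deviations, taken to cancel within each group, gave 19.1%, 19.6% and 18.7%.

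Before the data were examined, the tests, the alternatives, 20 lists of miRNAs and the rule for naming miRNAs were fixed. The rule took, for each treatment against control, all called miRNAs, filled up to 20 with the smallest unadjusted p among those whose treated arrays both lay above, or both below, both controls. For the other comparisons it took 10. It added the 10 brightest miRNAs in control and the members of the lists with the smallest p, and further list members, partner arms, let-7d, miR-1228 and miR-122 were named after their values were seen. The lists were the let-7 family, the miR-17 clusters, the miR-30 family and its passenger strands, the miR-200 family, liver-enriched miRNAs, lipid and glucose metabolism, p53-responsive and stress, hypoxia and redox, inflammation, oncomiRs of liver tumour lines, tumour-suppressive miRNAs, C19MC (by a number range that also takes in 5 miR-513 and miR-514 forms of the X chromosome), the 14q32 cluster, markers of blood cells, muscle, neural cells, and endothelium and stroma, all passenger strands, and late-registered miRNAs. For each treatment against control, for grape seed against cacao extract and for the average of the treatments, each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the 20 lists of a comparison. With the estimated correlation or with fry, 0 lists passed in any of these comparisons.

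The miRNA names are those of the tables, and 842 of 904 matched a gene of the RefSeq table for GRCh38.p14, which was used for names and for neighbours within 10 kb. No genome build is named in the sources used here, so no coordinates are given.

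The fit was tested on simulated data for grape seed extract against control, with 200 of 904 miRNAs changed, in 20 simulations. With independent arrays, limma called 39.2%, 81.9% and 85.6% of the miRNAs changed 2-fold, 4-fold and 8-fold, and 8.73% of its calls were false. With the deviations shared between arrays, taken to cancel within each group, it called 24.3%, 70.9% and 80.7%, with 2.20% false calls. These deviations were measured from the group means, so they cancel by construction. Any part of them that reached a group mean in the real data is left out of the simulations. The correlation of fold changes with shared controls was simulated 1000 times with independent arrays and 1000 times with the shared deviation cancelling within groups. The alternatives were the deposited values, no normalization, scaling to the 75th percentile, cyclic loess, offsets of 1 and 200, only the brighter 452 miRNAs, a trended robust variance prior, the replicate number as a block, only the arrays compared, and each array left out in turn.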

Results

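MicroRNAs (miRNAs) were measured on 8 single-colour arrays in HepG2 cells, an established human liver tumour line. The 4 groups of 2 arrays were untreated cells, cells given a cacao proanthocyanidin extract at 100 mg/L, cells given a grape seed proanthocyanidin extract at 100 mg/L, and cells given epigallocatechin gallate (EGCG) at 50 mg/L. Each treatment lasted 5 h. Proanthocyanidins are chains of flavan-3-ol units, and EGCG is a single flavan-3-ol unit, a catechin of green tea, esterified with gallic acid. The design compared each treatment with the untreated cells. The tables held 1 intensity for each of 904 human miRNAs on every array, and the number of arrays limits the precision of all values below. The series text calls the 2 arrays of a group biological replicates without saying whether they came from separate cultures, so the p-values measure the spread between these arrays, which may be partly technical.

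The brightest miRNAs in untreated cells were miR-720, miR-191, miR-17, miR-194, miR-1280, miR-26a, miR-1260, miR-106a, miR-192 and miR-23b. miR-192 and miR-194 are liver and gut miRNAs, miR-17 and miR-106a belong to related clusters that promote proliferation, and miR-720 and miR-1280 have since been reannotated as tRNA fragments. Their control means lay between 13.12 and 13.76 on the normalized log2 scale (n = 2), and probes of different miRNAs are not ranked against each other by abundance. None of these 10 differed from control in any treatment after adjustment, with a smallest adjusted p of 0.985 from limma. The nearest to a difference was miR-1260 in grape seed extract, at -0.65 (SE 0.27). miR-122, the main hepatocyte miRNA, was dim on these arrays, with a control mean of 7.44 ± 0.60 (SD, n = 2). Its log2 fold changes were 0.03 in cacao extract, -0.57 in grape seed extract and -0.49 in EGCG (SE 0.41 each).

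Before normalization the arrays differed in brightness. The median intensity was 80 and 116 on the control arrays, 120 on both cacao arrays and 72 and 176 on the grape seed arrays, and 64 on EGCG array 2. The summed intensity ran from 316334.5 on control array 2 to 711923.5 on control array 1. Between 1.44% and 13.5% of the 904 miRNAs per array had an intensity at or below 0 after the background subtraction. After normalization the correlation across miRNAs within a group was 0.906 for the controls, 0.956 for cacao extract, 0.953 for grape seed extract and 0.937 for EGCG. On every one of the 8 arrays the closest array belonged to another group, at r = 0.959 to 0.974. let-7d and miR-1228 were among the miRNAs that moved most between arrays of a group. The intensity of let-7d was 2145 and 232 in the controls and 392 and 1713 in cacao extract, and that of miR-1228 was 12779 and 1016 in the controls.

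**Figure D1:**
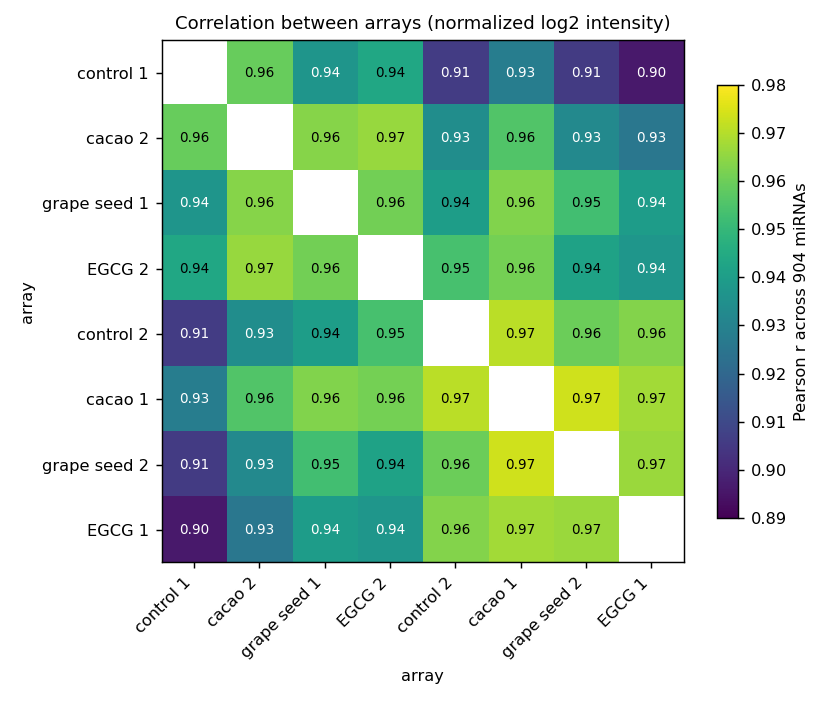
Pearson correlation (colour and number) between the 8 arrays across 904 miRNAs, on the normalized log2 intensity. Control 1, cacao 2, grape seed 1 and EGCG 2 are placed first, and control 1 correlates at 0.96 with cacao 2 but at 0.91 with control 2.

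With the main processing, 3 miRNAs stood above untreated cells past the adjusted threshold in grape seed proanthocyanidin extract. miR-1224-3p, the 3' arm of a hairpin described as a mirtron, which is spliced out as a short intron, rose 6.41-fold, from 9.54 ± 0.50 in control to 12.22 ± 0.28 in treated cells (log2, SD, n = 2). miR-449b*, the passenger strand of a member of the miR-449 family, which shares its seed with the p53-responsive miR-34, rose 3.93-fold, from 9.41 ± 0.62 to 11.38 ± 0.16. miR-1234, another miRNA described as a mirtron product, rose 3.30-fold, from 12.28 ± 0.30 to 14.01 ± 0.17. Both treated arrays lay above both control arrays for each of them, and no miRNA fell past the threshold.

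In limma the log2 fold changes were 2.68 for miR-1224-3p (SE 0.33, 95% interval 1.95 to 3.41, adjusted p = 0.0118), 1.97 for miR-449b* (SE 0.32, interval 1.26 to 2.69, adjusted p = 0.0370) and 1.72 for miR-1234 (SE 0.26, interval 1.13 to 2.32, adjusted p = 0.0370). Before normalization miR-1224-3p had intensities of 5521 and 4025 in grape seed extract against 1697 and 416 in control. The other arm of the same hairpin, miR-1224-5p, was dim, with a control mean of 7.29 ± 0.82 (SD, n = 2), and had a log2 fold change of -0.78 (SE 0.43). Across all 904 miRNAs, 29 had an unadjusted p under 0.05 (14 higher and 15 lower). Chance gives 45.2 for independent arrays, and unchanged groups simulated with the deviations that these arrays share gave 15.95. In 20 simulations of unchanged groups, limma called a mean of 0.25 and at most 3 miRNAs with independent arrays, and 0 with shared deviations. The simulations with shared deviations, here and below, took them to cancel within each group by construction. They may therefore understate what chance gives. The count of 3 became 0 with the authors' deposited values, without normalization between arrays, with 75th percentile scaling, with cyclic loess, with an offset of 1 or with only the control and grape seed arrays in the fit, and 1 (miR-1224-3p) with the replicate number as a block. It also became 0 without control array 2, cacao array 1 or either grape seed array, and 1 (miR-1224-3p) without cacao array 2 or either EGCG array.

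**Figure D2:**
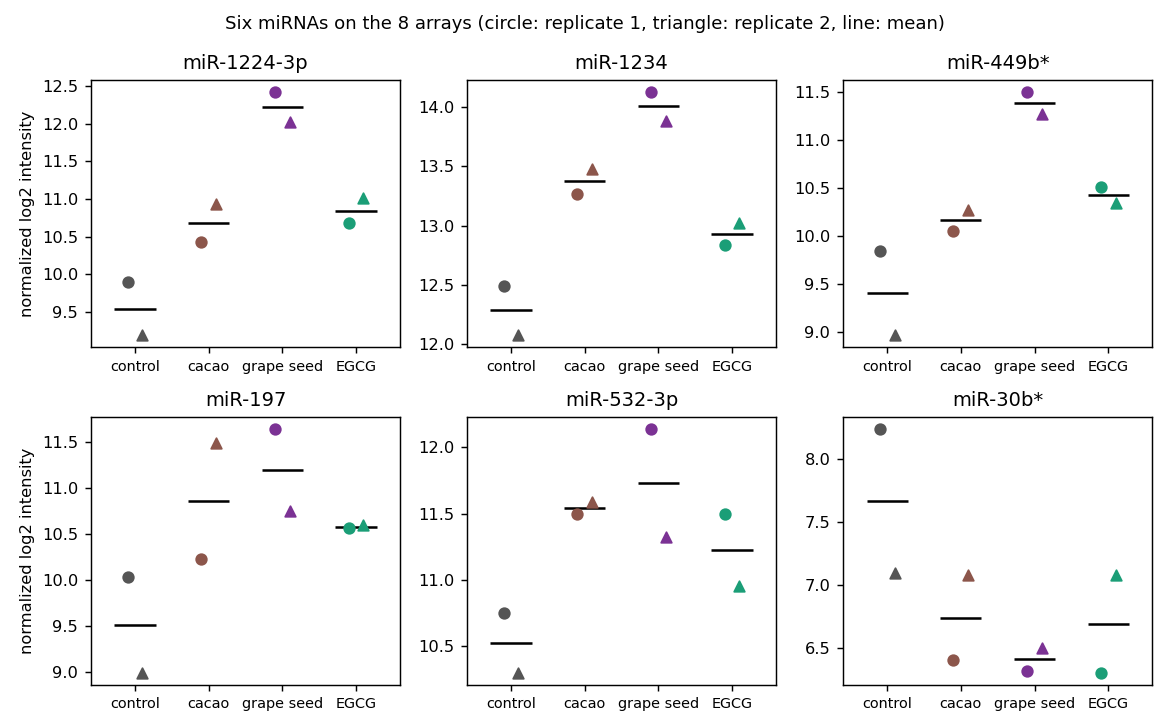
Normalized log2 intensity (vertical axis, a separate range in each panel) of 6 miRNAs on each array by group, with circles for replicate 1, triangles for replicate 2 and a line at the group mean. For miR-1224-3p the grape seed mean is 12.22 and the control mean 9.54, and for miR-30b* all 6 treated arrays lie below both control arrays.

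The other 17 miRNAs selected for grape seed extract did not pass the adjusted threshold (adjusted p = 0.712 to 0.985), and 7 of the 17 were dim, with a mean intensity below the median of all miRNAs. Among the bright ones, miR-210, which hypoxia induces, had a log2 fold change of -1.06 (SE 0.30, limma adjusted p = 0.712) and lay below both controls on 6 of 6 treated arrays of the 3 treatments. miR-197 had 1.69 (SE 0.49) and miR-532-3p had 1.20 (SE 0.34), each above both controls on 6 of 6 treated arrays. miR-361-5p had -1.15, miR-193b had -0.96, and miR-483-5p, which lies within the IGF2 gene, had a 95% interval of -1.89 to -0.11. miR-185 had -0.80, miR-93 of the miR-106b-25 cluster had -0.74, miR-99b had -0.72, and miR-1975, since reannotated as a Y RNA fragment, had 0.81. The dim ones were miR-30b* at -1.26, miR-453 at -1.05, let-7b* at -0.78, miR-522 at 0.90, miR-545* at 0.85, miR-15b* at 0.74 and miR-557 at 0.64.

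Among the 20 lists of miRNAs fixed beforehand, the miR-17 clusters, whose members promote proliferation, were lower in grape seed extract. Their median log2 fold change was -0.35, and 12 of 13 members were lower, among them miR-93 (-0.74), miR-19a (-0.49) and miR-20b (-0.44), while miR-363 was at 0.21. The list passed camera with its preset correlation (adjusted p = 0.00425) and did not pass with an estimated correlation (adjusted p = 0.582), and 0 of its members passed alone. Several of these miRNAs, such as miR-17, miR-20a, miR-20b, miR-93, miR-106a and miR-106b, have nearly identical sequences, and their probes may share signal. The list median was -0.11 with cyclic loess (adjusted p = 0.436), -0.55 without normalization between arrays (2.55e-06) and -0.61 with 75th percentile scaling (0.00106). Its adjusted p was 0.110 with the deposited values, 0.0614 with an offset of 1, and 0.0966, 0.0654 and 0.132 without control array 1, control array 2 and grape seed array 1.

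No other list passed in grape seed extract (camera, adjusted p of at least 0.289). The let-7 family, which restrains growth, had a median of -0.26 with 9 of 9 members lower, the miR-30 family had -0.12 with 3 of 5 lower, and the passenger strands of miR-30 had -0.15 with 6 of 6 lower. The epithelial miR-200 family had -0.10 with 4 of 5 lower. The liver-enriched list had -0.10 with 10 of 13 lower and miR-483-5p as the member with the smallest p. The lipid and glucose metabolism list had -0.14 with 13 of 21 lower, led by miR-185, and the hypoxia and redox list had -0.24 with 7 of 10 lower, led by miR-210. The p53-responsive and stress list had -0.11 with 8 of 12 lower, although its mean was 0.05, the inflammation list had -0.17 with 8 of 11 lower, the list of oncomiRs had -0.20 with 6 of 11 lower, and the tumour-suppressive list had -0.21 with 8 of 11 lower. The list for the placental cluster on chromosome 19 (C19MC), which by its number range also holds 5 miR-513 and miR-514 forms of the X chromosome, had a median of 0.07 over 64 members, or 0.05 over the 59 others, led by miR-522, and the imprinted 14q32 cluster had 0.09 over 51 members. Markers of cells that the culture should lack had medians of 0.07 for blood cells (mean 0.02, with a downward test), -0.18 for muscle, -0.08 for neural cells and 0.16 for endothelium and stroma. Passenger strands as a class had a median of 0.05 with 110 of 186 higher, and miRNAs registered late, had 0.02 with 78 higher and 73 lower. Adjusted over the list alone, miR-449b* passed among the passenger strands (adjusted p = 0.0228), and miR-1224-3p (0.00197) and miR-1234 (0.00657) passed among the late-registered miRNAs.

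**Figure D3:**
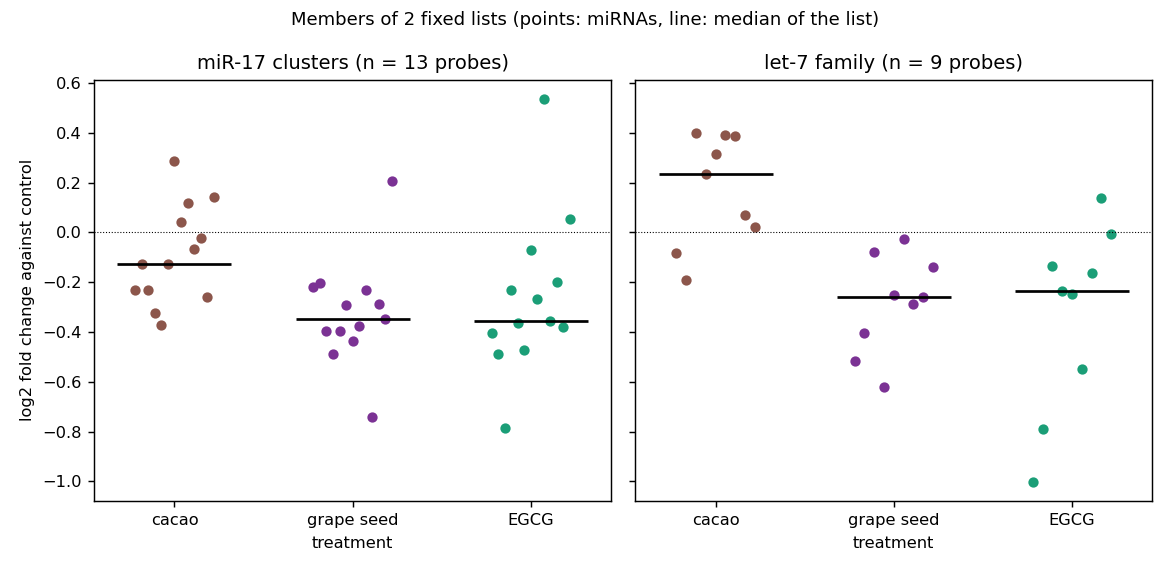
Log2 fold change against control (vertical axis) of each member of the miR-17 clusters and the let-7 family in the 3 treatments, with a line at the median of the list. The median of the miR-17 clusters lies at -0.13 in cacao extract, -0.35 in grape seed extract and -0.36 in EGCG, and that of the let-7 family at 0.23, -0.26 and -0.23.

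Cacao proanthocyanidin extract left every miRNA short of the adjusted threshold against untreated cells. The values closest to it were those of miR-1234, at a log2 fold change of 1.09 (SE 0.26), and miR-1224-3p, at 1.14 (SE 0.33), both above both controls on both cacao arrays. miR-197 had 1.35 (SE 0.49), miR-532-3p had 1.02 (SE 0.34) and miR-449b* had 0.76 (SE 0.32). On the lower side, miR-30b* had -0.92, miR-299-3p and miR-299-5p of the 14q32 cluster had -0.78 and -0.70, and miR-199b-5p, a stromal miRNA, had -0.76, all of them dim.

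limma called 0 of 904 miRNAs in cacao extract, with a smallest adjusted p of 1 and 15 miRNAs at an unadjusted p under 0.05 (7 higher and 8 lower, where chance gives 45.2 for independent arrays and 15.25 in the simulation with shared deviations). With the deposited values limma also called 0, with 5 at an unadjusted p under 0.05. The 20 selected miRNAs were 10 higher and 10 lower, and 12 of them were dim. The others were miR-557 at 0.78, miR-10a* at 0.58, miR-767-3p and miR-545* at 0.55 each, miR-1257 at 0.52, miR-934 at -0.66, miR-520e at -0.65, miR-1269 at -0.63, miR-642 and miR-1271 at -0.59 each and miR-602 at -0.54. No list passed camera (adjusted p of at least 0.847), and the list medians ran from -0.13 for the miR-17 clusters (9 of 13 lower) to 0.23 for the let-7 family (7 of 9 higher). The liver-enriched list, the oncomiRs, the passenger strands, and the blood-cell and neural markers had medians and means of opposite sign, each median within 0.03 of 0. The median 95% interval reached 0.675 to either side of a log2 fold change.

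EGCG also left every miRNA short of the adjusted threshold. The largest values among bright miRNAs selected for EGCG were those of miR-1224-3p, at a log2 fold change of 1.30 (SE 0.33), and miR-449b*, at 1.02 (SE 0.32), both above both controls on both EGCG arrays. miR-1234 had 0.64 (SE 0.26) and miR-1975 had 0.73 (SE 0.30). On the lower side, the dim miR-30b* had -0.98 (SE 0.42), miR-200b, which maintains the epithelial state, had -0.74 (SE 0.30), and the dim miR-375, best known from pancreatic islets, had -0.67 (SE 0.26).

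limma called 0 of 904 miRNAs in EGCG, with a smallest adjusted p of 0.999 and 19 at an unadjusted p under 0.05 (11 higher and 8 lower, with chance values of 45.2 for independent arrays and 14.8 with shared deviations). With the deposited values limma also called 0, with 10 at an unadjusted p under 0.05. Of the 20 selected miRNAs 11 were higher, 9 were lower and 12 were dim. The others were miR-625* at 0.73, miR-10a* at 0.71, miR-519b-3p at 0.70, miR-513a-3p at 0.68, let-7a* at 0.67, miR-875-3p and miR-943 at 0.64 each, miR-453 at -0.81, miR-609 at -0.74, miR-520e at -0.65, miR-513c and miR-1322 at -0.64 each and miR-220b at -0.60. miR-1975 had -0.038 without normalization between arrays. The miR-17 clusters were lower, with a median of -0.36 and 11 of 13 members lower, among them miR-18b (-0.79) and miR-18a (-0.49), while miR-92a was at 0.54. This list passed camera with its preset correlation (adjusted p = 0.0195) and did not pass with an estimated correlation (adjusted p = 0.775). The median was -0.96 without normalization between arrays (adjusted p = 2.25e-08), -0.91 with 75th percentile scaling (0.000252), -0.70 with the deposited values (0.00238), -0.21 with cyclic loess (0.132) and -0.23 without EGCG array 1 (0.560). The adjusted p was 0.182 with an offset of 1, and 0.150 and 0.225 without control array 1 and control array 2. The other 19 lists did not pass (adjusted p of at least 0.248). The endothelial and stromal markers had a median of 0.00 and a mean of -0.03.

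Averaged over the 3 treatments, miR-1224-3p stood 3.26-fold above control (log2 1.71, SE 0.27), miR-449b* 2.38-fold (log2 interval 0.67 to 1.83) and miR-1234 2.22-fold (log2 1.15, SE 0.22), each above both controls on 6 of 6 treated arrays. miR-197 had 1.37, miR-532-3p had 0.97, miR-1975 had 0.67 and miR-557 had 0.62. miR-30b*, the passenger strand of miR-30b, had -1.05, miR-210 had -0.72 and miR-520e of C19MC had -0.65, each below both controls on 6 of 6 treated arrays. In all, 44 of 904 miRNAs (4.87%) had all 6 treated arrays on one side of both controls, where chance gives 7.14% for independent arrays and the simulation with shared deviations gave 3.67%. Among the 10 miRNAs named for this average, miR-30b*, miR-520e and miR-557 were dim. The partner of miR-30b*, miR-30b, was bright and had 0.20 (SE 0.23).

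None of the 904 miRNAs passed in this average (limma, adjusted p = 0.0897 for miR-1224-3p, 0.179 for miR-1234 and 0.243 for miR-449b*), and 22 had an unadjusted p under 0.05 (14 higher and 8 lower). With the deposited values limma called 0, with 8 at an unadjusted p under 0.05. Adjusted over the list alone, miR-1224-3p (0.0150) and miR-1234 (0.0300) passed among the late-registered miRNAs. The test for any difference among the 4 groups also called 0, with 13 at an unadjusted p under 0.05 and a smallest adjusted p of 0.108 for miR-1224-3p, and 0 and 5 with the deposited values. The miR-17 clusters had a median of -0.29 with 11 of 13 lower and passed camera with its preset correlation (adjusted p = 0.0178), but not with an estimated correlation (adjusted p = 0.809). The median was -0.49 with 75th percentile scaling (adjusted p = 0.00322) and -0.12 with cyclic loess (0.382). The adjusted p was 0.0960 with the deposited values, 0.214 with an offset of 1, and 0.538, 0.268, 0.110 and 0.109 without control array 1, control array 2, grape seed array 1 and EGCG array 1. The p53-responsive and stress list had a median of -0.09 and a mean of 0.03.

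Grape seed and cacao extracts were compared directly, since their doses by mass and their times matched. miR-1224-3p stood 2.91-fold higher in grape seed than in cacao extract (log2 1.54, SE 0.33, 95% interval 0.81 to 2.27), and miR-449b* 2.32-fold higher (log2 1.22, SE 0.32, interval 0.50 to 1.93). miR-20b and miR-93 of the miR-17 clusters had -0.72 and -0.67, and miR-324-5p had -0.71. The dim miRNAs miR-145*, miR-155*, miR-642 and miR-522 had 0.75, 0.73, 0.67 and 0.64, and miR-1257 had -0.66. The let-7 family was lower in grape seed than in cacao extract, with a median of -0.43 and 9 of 9 members lower, among them let-7d (-0.85) and let-7g (-0.68). It passed camera with its preset correlation (adjusted p = 0.0282) but not with an estimated correlation (0.630), and without cacao array 2 its median was -0.16 with 6 of 9 lower (0.980).

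limma called 0 miRNAs between the extracts (smallest adjusted p = 0.861), with 16 at an unadjusted p under 0.05, and with the deposited values 0 and 6. The miR-17 clusters (median -0.16, 11 of 13 lower) also passed camera with its preset correlation (adjusted p = 0.0282) and not with an estimated correlation (0.484). Taken over all groups together, the 9 let-7 members went in one direction along the main pattern of differences between arrays of a group. The let-7 median became -0.24 (adjusted p = 0.498) without grape seed array 2, -0.93 (0.000344) without cacao array 1, -0.76 (0.0130) with the deposited values, -0.73 (9.13e-05) without normalization between arrays, -0.72 (0.232) with an offset of 1 and -0.57 (0.0593) among the bright members. The miR-17 median became -0.58 without normalization, -0.44 with 75th percentile scaling, -0.42 with the deposited values, -0.06 (0.767) with cyclic loess, and -0.25 (0.0973) and -0.31 (0.409) without cacao array 1 and grape seed array 1, and its adjusted p was 0.232 with an offset of 1. The blood-cell markers had a median of -0.04 and a mean of 0.06.

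EGCG was given at 50 mg/L and the extracts at 100 mg/L, so their values stand side by side without a matched dose. Against grape seed extract, EGCG had miR-1224-3p at -1.38 (SE 0.33), miR-1234 at -1.08 (SE 0.26), miR-143 at -1.12, miR-449b* at -0.96, miR-193b at 0.97 and miR-1260 at 0.82. The dim miR-522, miR-27a*, miR-513c and let-7b* had -0.77, -0.77, -0.72 and 0.86. Against cacao extract, EGCG had miR-328 at -0.92, miR-1238 at -0.83, miR-625 at -0.76, miR-885-5p at -0.67, miR-375 at -0.59, miR-199b-5p at 0.77, miR-769-5p at 0.74, miR-132* at 0.73, miR-299-5p at 0.70 and miR-620 at 0.65, and 9 of these 10 were dim. limma called 0 miRNAs in either comparison (smallest adjusted p = 0.994 and 0.995), with 24 and 10 at an unadjusted p under 0.05, and with the deposited values 0 in both, with 12 and 6. With an offset of 1, miR-132* passed between EGCG and cacao extract.

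The fold changes of the 3 treatments were correlated across miRNAs. The miRNAs miR-1224-3p, miR-1234, miR-449b* and miR-30b* were selected in all 3 treatments, and 8 others in 2 treatments. Unchanged groups simulated against the same controls, with the same selection, gave means of 1.45 (SD 1.19) and 7.10 (SD 2.88) for independent arrays, and 1.60 (SD 1.35) and 7.90 (SD 1.92) with shared deviations. Pearson's r was 0.611 between cacao and grape seed extracts, 0.536 between cacao extract and EGCG, and 0.607 between grape seed extract and EGCG. Unchanged groups simulated against the same 2 control arrays gave r between 0.499 and 0.501 (SD 0.039), and miRNAs are not independent replicates. The covariances were 0.0630, 0.0475 and 0.0696 against simulated values of 0.0713, 0.0712 and 0.0712, differences of -0.00839, -0.0237 and -0.00157. That simulation drew independent arrays. With the deviation that the arrays share taken to cancel within each group, the simulated covariances were 0.0387, 0.0389 and 0.0389 (SD 0.005), differences of 0.0243, 0.00862 and 0.0308, and r was 0.496 to 0.498 (SD 0.041 to 0.042). Both simulations gave every group the same spread, whereas the median SD between arrays was 0.303 in control and 0.188 to 0.228 in the treatments, and a wider spread of the controls raises r without any effect. The fold changes had the same sign for 66.4%, 64.9% and 68.7% of the miRNAs, where the simulation gave 66.7%, 66.6% and 66.7%. The controls could not be split into parts of 2 arrays, so part or all of the correlation may come from the shared control arrays.

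**Figure D4:**
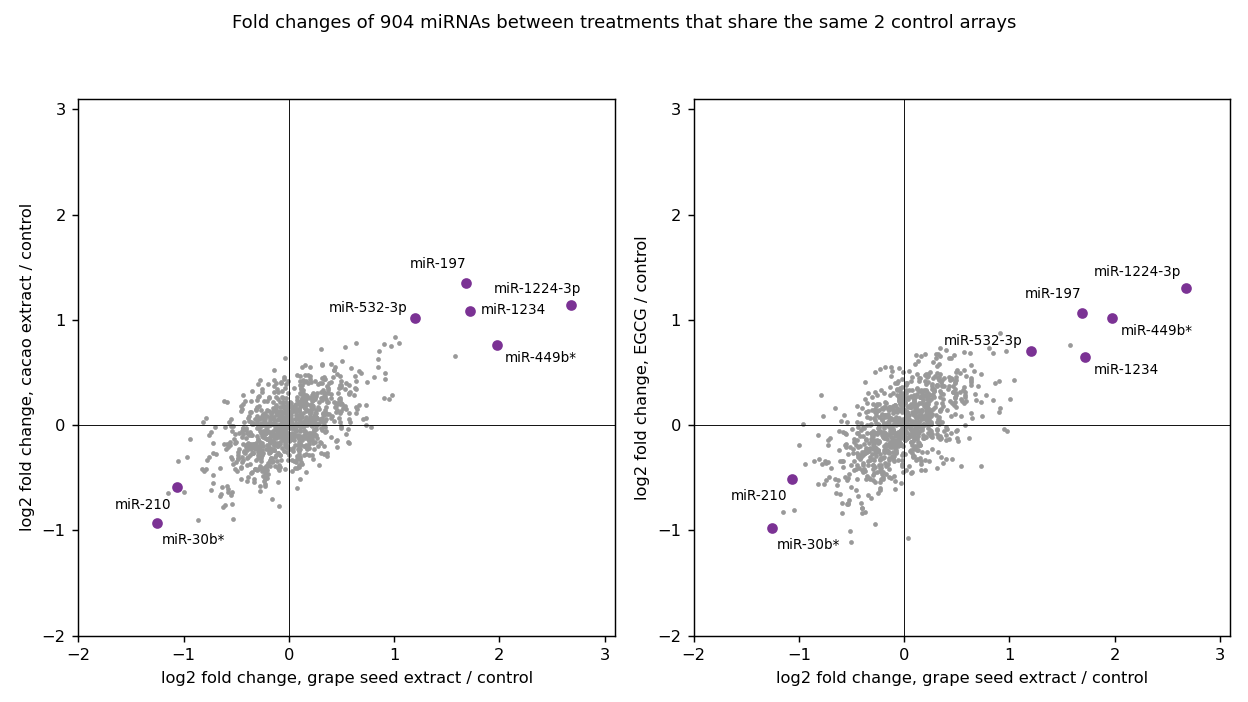
Log2 fold changes of 904 miRNAs against control, with grape seed extract on the horizontal axis and cacao extract (left) or EGCG (right) on the vertical axis. Each point is a miRNA, 7 of them are named in purple, and miR-1224-3p lies at 2.68 in grape seed extract, 1.14 in cacao extract and 1.30 in EGCG.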

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

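The fit with a crossed replicate block was chosen after seeing the data, and the other alternatives beforehand. Grape seed extract against control had 3 calls. It had 0 with the deposited values, no normalization between arrays, 75th percentile scaling, cyclic loess, an offset of 1 or only the arrays compared, and 1 (miR-1224-3p) with the replicate block. It had 2 with an offset of 200 or the trended robust prior (both miR-1224-3p and miR-1234) and 3 among the brighter miRNAs. Leaving out each array gave 0 to 3 calls there (19 to 114 at an unadjusted p under 0.05) and 0 in every other comparison. A lone array was then assumed to vary like those of the other groups. Over all these settings the log2 fold change stayed above 0, at 2.34 to 2.99 for miR-1224-3p, 1.31 to 1.96 for miR-1234 and 1.51 to 2.32 for miR-449b*. The standard error of miR-1224-3p grew from 0.33 to 0.70 with the deposited values and to 0.78 with 75th percentile scaling. Its log2 fold change was 2.67 and 2.34 there, against 2.68 in the main fit. The cause of the larger spread was not tested.

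The other comparisons kept 0 calls under the planned settings, except EGCG against cacao extract with an offset of 1 (1 call, miR-132*). The replicate numbers did not pair the arrays: deviations of the arrays numbered 1 correlated between groups at -0.52 to 0.44, and the replicate block changed no other count and added 1 list call. With a crossed replicate block, which exchanges the numbers in cacao extract and EGCG, grape seed extract had 4 calls, its comparisons with cacao extract and with EGCG 1 each, the average of the treatments 4 and the test of any difference 3, while 1 of the 5 list calls was lost (the miR-17 clusters between grape seed and cacao extracts).

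The correlation of fold changes moved to 0.542 (cacao and grape seed extracts) and 0.460 (cacao extract and EGCG) with the deposited values, and to 0.668 (grape seed extract and EGCG) with cyclic loess. It moved to 0.488 (cacao extract and EGCG) and 0.701 (grape seed extract and EGCG) both without normalization and with 75th percentile scaling. That scaling only subtracts a constant from each array, so r had to be the same in both settings. Without normalization between arrays, 3 directions reversed: miR-1975 in EGCG (from 0.73 to -0.038), and the median of the passenger strands in EGCG (from 0.03 to -0.0018) and between grape seed and cacao extracts (from 0.07 to -0.000771). The cause was not tested. Of the values of named miRNAs under alternatives, 1789 kept direction and side of the threshold, 40 lost the threshold and 8 gained it. All 40 losses were of the 3 miRNAs called in grape seed extract against control. The 1789 were mostly values of miRNAs that the main fit did not call. Those miRNAs had been selected with treated arrays beyond both controls, which largely fixed their direction, so the 1789 do not measure how stable the calls were. Among the tests of lists with a preset correlation, 27 calls were lost and 70 gained. Most of the gains came without normalization or with 75th percentile scaling. A fit without any background correction was not run, because the deposited intensities were already subtracted. At most 13.5% of the miRNAs of an array had no signal above 0, but dim miRNAs lie close to the floor, which limits their fold changes.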

Other observations

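The fits with other normalizations, with the deposited values and without single control arrays were planned, but the bounds they are read against here were written after the results were seen. The tests of named batches, of monotone distortion and of the partners of miR-1224-3p and miR-1234 apart, and the simulations with a shared deviation, were chosen after the results, and the mirtron list was drawn up after the calls. Mirtrons are miRNAs made from short spliced introns. In grape seed extract, their 5' arms, 5 miRNAs that include miR-877, miR-1224-5p and miR-1225-5p, had a median log2 fold change of -0.46 with 4 of 5 lower (camera p = 0.0440, and p = 0.231 with an estimated correlation). In cacao extract and EGCG these 5 had medians of -0.27 and -0.19. The 3' arms without miR-1224-3p and miR-1234, 10 miRNAs, had medians of 0.16 in cacao extract and -0.10 in EGCG. The neighbours of miR-532-3p within 10 kb, 7 miRNAs of the miR-188 to miR-532 cluster that include miR-362-3p and miR-501-3p, had log2 fold changes of -0.32 to 0.53 in grape seed extract, against 1.20 for miR-532-3p itself and -0.02 for miR-532-5p of the same hairpin.

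The first pattern is the rise of miR-1224-3p, miR-449b* and miR-1234 in grape seed extract. Over the 4 other normalizations, the rise of miR-1224-3p and miR-449b* kept its direction, with a lowest log2 fold change of 1.51 (2.17 standard errors). The bound that this met was written after the results, and miR-1234 fell short of it (1.305, 1.65 standard errors). The calls of all 3 ended there, where the standard errors were larger and the log2 fold change of miR-449b* was below its main value of 1.97. Normalization as the source of the calls therefore stays open for all 3. With either control array left out, the lowest of the 3 log2 fold changes was 1.509, which met the bound. All 3 had been called with both treated arrays above both controls, which largely fixed that sign, so this does not decide on a single control array. A general rise of mirtron 3' arms is argued against by the other 10, at a median of -0.050 (SE 0.20). For miR-1224-3p, a rise of the whole hairpin is argued against by the log2 fold change of miR-1224-5p, -0.78 (SE 0.43). For miR-1234, a rise shared with its neighbour miR-939 is argued against by that of miR-939, -0.545 (SE 0.54). Both readings hold as far as the dim signal of these partners is that of the miRNA, and each rests on 1 partner. No other arm of the miR-1234 hairpin was among the partners, so a rise of that hairpin was not tested. For miR-449b*, a rise of the whole hairpin or cluster cannot be told apart from a rise of this arm alone. The median of all 6 partners, -0.078 (SE 0.22), met the bound of 1 written beforehand. That bound was wrong to use for the 4 partners of miR-449b*, whose control means lay within 1 of the floor. An effect of the extract on the cells or on the assay's probes was not tested. Since whether the untreated cells received DMSO is not given, the design cannot separate such an effect from one of DMSO.

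The second pattern is that the arrays of a group differed from each other along a direction shared between groups. Control array 1, cacao array 2, grape seed array 1 and EGCG array 2 deviated together, along an axis that held 58.9% of the variation within groups, which was itself 66.5% of all variation, and let-7d, let-7c, miR-1228, miR-1207-5p and miR-149* were among its strongest members. The normalization used here as the source is argued against by the deposited values, where the smallest absolute correlation of deviations between groups was 0.429. A monotone distortion of whole arrays with intensity is argued against, since quantile normalization removes it and the smallest absolute correlation left was 0.372, whereas a distortion of another shape cannot be told apart, because that normalization itself holds Spearman's rho between loading and mean intensity (-0.102) near 0. The labels name 0 batches, so a culture, labelling or hybridization batch stays open, and may have been numbered differently in cacao extract and EGCG.

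The third pattern is the correlation between the fold changes of the 3 treatments. The shared control arrays cannot be told apart from a shared response: the largest covariance lay -0.00157 from the simulated one, and that of cacao extract and EGCG lay -0.0237 from it. A shared response could also be one to DMSO, which all treatments held at 0.1%. Whether the untreated cells received DMSO is not given, so the design cannot separate it from the compounds. The bound written beforehand was wrong, because the simulation drew independent arrays, whereas a deviation with 1 array of each group on either side widens the spread within groups and cancels between group means. With that deviation taken to cancel, the covariances lay 0.0243, 0.00862 and 0.0308 above the simulated ones (SD 0.005), the labels do not give whether it is such a batch, and the simulated r (0.496 to 0.501 in both) rests on equal spread in all groups, whereas the median SD was 0.303 in control and 0.188 to 0.228 in the treatments. Simulated unchanged groups gave a mean of 45.6 miRNAs at an unadjusted p under 0.05 with independent arrays and 15.95 with the shared deviation, again taken to cancel. Grape seed extract had 29. In the same simulations 7.02% and 3.67% of miRNAs had all 6 treated arrays beyond both controls, against 4.87% observed.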
